A study of Capra hircus with 14 samples.

How the data were processed

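Transcript abundance was measured by RNA sequencing in the Longissimus thoracis, a back muscle, of newborn male goat kids (Capra hircus, Saanen dairy breed). There were 14 libraries, 8 from kids of does fed at maintenance early and restricted late in gestation (MR) and 6 from kids of does restricted early and fed at maintenance late (RM). Per the labels, RNA was extracted with a column kit for fibrous tissue and sequenced on an Illumina HiSeq instrument as paired reads of 150 bases. Each group was taken from the sample titles. The replicate numbers in the titles are not shared between groups, so no pairing was possible, and the labels give no litter, batch or date.

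The authors deposited 1 table of FPKM (fragment counts scaled by transcript length and by the mapped fragments of the library) with 1 row per transcript, per the labels and the file header. The label of RM replicate 6 refers to raw counts where the others refer to FPKM, but the values are not whole and no value has more than 2 decimals, and the libraries sum to different totals. Reads were trimmed with Trimmomatic and aligned with HISAT2 2.0.5, per the submitters' processing notes. The genome build, the annotation, the assembler, any filter and the way in which libraries were joined are not given in the sources used here. The table has 65535 rows under 1 header line, which together fill the row limit of an older spreadsheet format. Of these rows, 19534 carry Ensembl goat transcript identifiers (reference transcripts below) and 46001 carry identifiers of the form CUFF.locus.isoform (CUFF rows below).

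No row has a gene symbol. The table of goat genes used here lists 28911 genes, of which 0 have an Ensembl identifier, so 0 of the transcripts were matched to a gene. The 27 gene lists (647 genes) chosen for this tissue, the fibre type balance and the developmental myosin score were therefore not analysed here, and neither were genomic positions. Transcripts are given by identifier.

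Tests, alternatives and gene lists were fixed before the data were examined. FPKM values were put on a log2(FPKM + 1) scale, rows with a mean of at least 0.5 FPKM over the 14 libraries were kept (37690 rows: 7025 reference transcripts and 30665 CUFF rows), and RM was compared with MR by limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. All fold changes are on that scale, which understates the change of low transcripts. The pseudocount is 1 FPKM. Rows with an assembler identifier formed the class of unannotated transcripts. Separation of the groups was tested by the ratio of the sum of squares between groups to that within groups, and the spread by the mean Euclidean distance of libraries to their own group mean, both by exact permutation over the 3003 splits of 14 libraries into 6 and 8. Per-library measures were compared by an exact two-sided permutation test of the difference in means.

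Because values of CUFF rows did not correlate between libraries, 3 fits were added after the data were seen: reference transcripts alone, the 1254 reference transcripts that were above 0 in all 14 libraries and passed the filter, and reference transcripts with values of 0 treated as missing (at least 4 values above 0 in each group). Separation and spread were also computed over the rows up to the end of the block of the first library, without that library, because later rows depend on where the table ended. The rule for named genes, fixed beforehand, asked for gene symbols. With none, 4 reference transcripts with a mean of at least 1 FPKM are named: for each direction, the one with the smallest p in the fit of all rows and the one with the smallest p among those above 0 in all libraries. This rule was set after the data were seen. The 3 CUFF rows with the smallest p are given as values without their identifiers. The other alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 1 or 5 FPKM, 3 other scalings, library weights, a robust variance prior, an adjusted p under 0.10, an exact Mann-Whitney test and leaving out each library in turn.

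Per the labels the mean was about 23000000 raw reads per library. The table has no read counts, so the depth of each library is known only relative to the others, and no interval or floor per library is given. A relative depth for each library was estimated from the most frequent ratio of the same low reference transcript between 2 libraries, over values from 0.1 to 0.6 FPKM (median peak 3.31 times the background), and 78 of 91 pairs of libraries fell within 0.05 log2 of it. Relative depth ran from 0.766 to 1.21 of the mean. No 2 columns were identical. The fits were tested on simulated data, made by shuffling each row's values over the libraries and multiplying 200 rows in 1 group by a known fold. Over all 37690 rows, 2-fold and 4-fold changes were recovered in 0% and 16-fold changes in 4% of the changed rows. Over the 7025 reference transcripts, 4-fold changes were recovered in 15.5% and 16-fold changes in 25.5%. Over the 1254 reference transcripts above 0 in all libraries, 2-fold changes were recovered in 51.5% and 4-fold changes in 96.5%. The 200 changed rows are a larger share of a smaller set, which eases the Benjamini-Hochberg threshold there. Recovery is therefore not comparable between sets and may be lower where fewer transcripts change. Figures were drawn with matplotlib 3.10.9.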

Results

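The series compared the timing of the same feed restriction in pregnancy. Of 60 does inseminated with semen of 1 buck, those of the MR group received 100% of their maintenance requirement on days 8 to 84 and 50% from day 85 until they gave birth. Does of the RM group received 50% on days 8 to 84 and 100% from day 85. Muscle of newborn male kids was sequenced in 8 MR and 6 RM libraries. There was no group fed at maintenance throughout, so each value below sets late against early restriction, and differences are RM minus MR. The labels do not say which kids shared a dam, so p-values measure only the spread between these samples, which litters would make too small.

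Deposited FPKM summed to 553909 ± 51254 per MR library (SD, n = 8) and 492591 ± 55515 per RM library (SD, n = 6; exact permutation p = 0.0546, adjusted p = 0.200 over 11 library measures). The lower sum in RM came from CUFF rows, which differed by -70576 and depend on where the table ended. Reference transcripts, those with Ensembl identifiers, contributed 171293 ± 13766 in MR and 180551 ± 10560 in RM (exact permutation p = 0.194, two-sided; 0.371 after Benjamini-Hochberg adjustment over 11 library measures). A library listed between 7649 and 8538 reference transcripts above 0. Expression was concentrated, and the 10 most abundant reference transcripts of each library held 24.7% ± 5.59 (SD, n = 8) of its reference FPKM in MR and 24.6% ± 3.89 (SD, n = 6) in RM, a difference within the spread between libraries (exact permutation p = 0.968). Relative depth, estimated from the most frequent ratio of low values between libraries, was 1.02 ± 0.165 (SD, n = 8) in MR and 0.979 ± 0.0988 (SD, n = 6) in RM (exact permutation p = 0.607). The estimate takes low values as steps of a few fragments, which was not settled. Scaled by it, transcripts of 0.3 to 1 FPKM gave 8.18% of pairs of values within 0.1 log2, against 38.4% for few fragments.

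Of the 10 reference transcripts with the highest mean, 5 were above 0 in every library, and none of the 10 passed the test between RM and MR (limma, smallest adjusted p = 0.857). The most abundant reached 7058 ± 3094 FPKM (SD, n = 8) in MR and 6156 ± 3739 FPKM (SD, n = 6) in RM. Its log2 difference was -0.25 with an SE of 0.44. The transcript ranked 3 reached 5122 ± 1786 and 5295 ± 2266 FPKM, a log2 difference of 0.04 with an SE of 0.23. The transcript ranked 9 had 2194 ± 347 FPKM in MR and 2204 ± 548 FPKM in RM, with a log2 difference of -0.01 (SE 0.14). The other 5 were listed at 0 in 1 to 4 libraries. Their log2 differences were 1.37, 2.47, 1.87, 3.13 and 2.41, with SEs from 1.45 to 2.68 (limma, smallest unadjusted p = 0.115). The transcript ranked 2 was listed at 0 in 3 libraries and between 2701 and 11635 FPKM in the others.

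No transcript passed the test between RM and MR. Over all 37690 rows, 0 were higher and 0 lower in RM at an adjusted p under 0.05 (limma, smallest adjusted p = 0.857). At an unadjusted p under 0.05 there were 1004 rows (2.66%), 680 higher and 324 lower in RM. In simulated data this fit recovered 4% of 16-fold changes. The exact Mann-Whitney test gave 963 rows at an unadjusted p under 0.05 and 0 after adjustment. With 6 against 8 libraries at least 252 rows would have to reach its smallest p, 3.33e-04, for any call. Only rows with tied values can reach that p in this two-sided test, and rows without ties would need more. Among the 7025 reference transcripts fitted alone, 0 passed (limma, smallest adjusted p = 0.1001), with 174 higher and 74 lower at an unadjusted p under 0.05. The exact Mann-Whitney test gave 217 transcripts at that level and 0 after adjustment, where a call needs at least 47 at its smallest p. With values of 0 as missing, 3713 reference transcripts were fitted and 0 passed (limma, smallest adjusted p = 0.0916). Of these, 93 were higher and 41 lower in RM at an unadjusted p under 0.05. ENSCHIT00000038172 and ENSCHIT00000023580, described below, had too few values above 0 for that fit.

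The comparison was sharpest for the 1254 reference transcripts that were above 0 in every library. Their median log2 difference was 0.06 and the median size of the difference was 0.16, against a median SE of 0.24. For 1098 of them (87.6%) the 95% confidence interval lay within a 2-fold difference in either direction, and for 437 (34.8%) within a 1.5-fold difference. These bounds are on the log2(FPKM + 1) scale, which understates the change of low transcripts. The share within 2-fold was 94.9% of the 470 with a mean of 0.5 to 5 FPKM, 84.7% at 5 to 20 and 81.5% at 20 to 100. Of the 100 with a mean of 100 FPKM or more, 81 had an interval within 2-fold. In this fit 0 transcripts passed (limma, smallest adjusted p = 0.978), with 27 higher and 11 lower in RM at an unadjusted p under 0.05. The exact Mann-Whitney test gave 44 at that level and 0 after adjustment. A call would need at least 9 at a p of 3.33e-04, and more than that for transcripts without tied values, which cannot reach it. Rescaling each library to the same sum moved their median difference from 0.06 to 0.22, and quantile normalization moved it to 0.20. Median-of-ratios scaling moved it to 0.01. That value says nothing on the shift, since this scaling sets its factors on rows above 0 in all libraries, nearly the same transcripts. The sum used for rescaling includes CUFF rows, whose mean sum was lower in RM and depends on where the table ended.

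**Figure D1:**
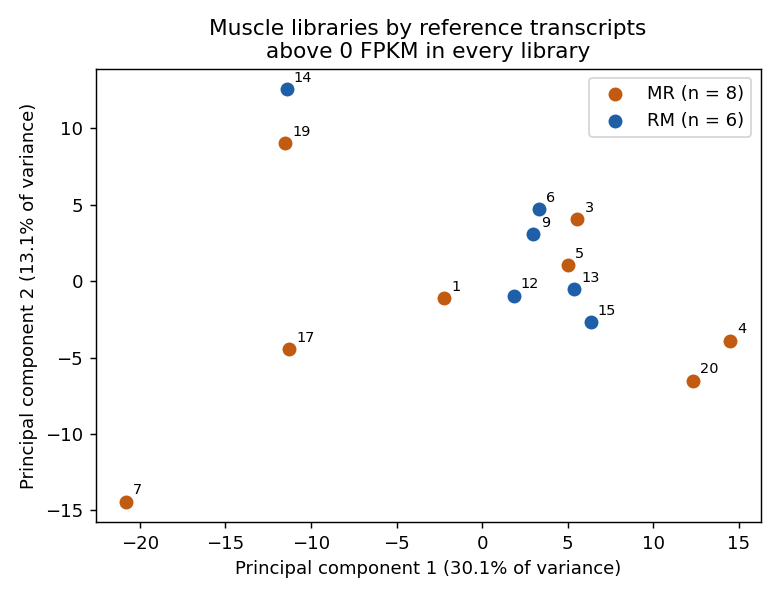
Principal components of log2(FPKM + 1) over the 1254 reference transcripts above 0 in every library. Each point is 1 library with its replicate number, and the axes are unitless scores. RM and MR libraries overlap on both axes, with MR scores from -20.8 to 14.5 on the first component.

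No separation of the feeding groups as wholes was detected. Over reference transcripts above 0 in all libraries, the ratio of the sum of squares between groups to that within groups was 0.0704, and the median over all 3003 splits was 0.0759 (exact permutation p = 0.619). Over all reference transcripts it was 0.0818 (exact permutation p = 0.532), and over all rows 0.0780, with a median of 0.0830 over the splits (exact permutation p = 1.00). The value over all rows says little on the feeding groups, since 30665 of the 37690 are CUFF rows. Their values did not correlate between libraries, and which of them are listed depends on where the table ended. The first principal component held 30.1% of the variance, and its difference between groups lay within the spread between libraries (exact permutation p = 0.669).

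MR libraries lay farther from their group mean than RM libraries in the measures below, but the test over all rows and over CUFF rows was not separate from where the table ended. Over all rows the mean distance was 258 log2 units in RM and 290 in MR (exact permutation p = 6.66e-04, two-sided). The difference of -31.8 was -49.6 with a pseudocount of 0.1 FPKM and -20.6 after quantile normalization. Over CUFF rows alone it was 238 and 269 (exact permutation p = 6.66e-04). After the last row of the first library, 30605 CUFF rows were first seen in an MR library and 141 in an RM library. Over the rows before that point, without that library, the mean distance was 193 in RM and 202 in MR (exact permutation p = 0.181). Over reference transcripts it was 99.9 and 106 (exact permutation p = 0.437), and over those above 0 in all libraries 14.3 and 18.7 (exact permutation p = 0.0593). As a percent of the MR distance the difference was -11.0% over all rows, -6.02% over reference transcripts and -23.7% over those above 0 in all libraries. The p over the last depended on single libraries: it was 0.00466 without RM replicate 14, 0.0303 without MR replicate 1, 0.0291 without MR replicate 5, and between 0.0571 and 0.118 without each of the others.

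Reference transcripts are named by the smallest p per direction, in the fit of all rows or of those above 0 in all libraries. None passed adjustment, and the fit with values of 0 as missing was not used for naming. ENSCHIT00000038172 was above 0 in all 6 RM libraries, at 26.5, 20.3, 16.8, 24.6, 15.5 and 17.7 FPKM, and in 1 of 8 MR libraries, replicate 5, at 17.9 FPKM. Its log2 difference was 3.85 (SE 0.69, limma adjusted p = 0.857 over all rows and 0.1001 over reference transcripts), and 6.70 with a pseudocount of 0.1 FPKM. Without MR replicate 5 it is listed at 0 in every MR library, and limma then gives an adjusted p of 1.09e-04 over all rows. The MR value above 0 lay within the RM range, so the difference rests on values of 0. Such values made up 41.7% of values of reference transcripts with a median of 10 to 100 FPKM where above 0. The difference need not be a change in expression. ENSCHIT00000025662, above 0 in every library, had 768 ± 195 FPKM (SD, n = 6) in RM and 415 ± 162 FPKM (SD, n = 8) in MR. Its log2 difference was 0.94 (95% interval 0.41 to 1.46, limma adjusted p = 0.978 among transcripts above 0 in all libraries), with 6 of 6 RM libraries above the MR median.

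In the other direction, ENSCHIT00000023580 was listed between 72.1 and 391 FPKM in all 8 MR libraries, and in RM at 105 and 93.6 FPKM in replicates 12 and 13 and at 0 in the other 4. Its log2 difference was -4.75 (SE 1.09, limma adjusted p = 0.857). That difference rests on the values of 0, since the RM values above 0 lay within the MR range. Values of 0 made up 34.3% of values of reference transcripts at this level, so it need not be a change in expression. ENSCHIT00000041532 had 18.9 ± 3.18 FPKM (SD, n = 6) in RM and 31.3 ± 7.47 FPKM (SD, n = 8) in MR. Its log2 difference was -0.68 (95% interval -1.53 to 0.17 in the fit of all rows, limma adjusted p = 0.857, and -1.09 to -0.27 among transcripts above 0 in all libraries, adjusted p = 0.978), with 6 of 6 RM libraries below the MR median. None of these 4 transcripts was matched to a gene, and their function is not given here.

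**Figure D2:**
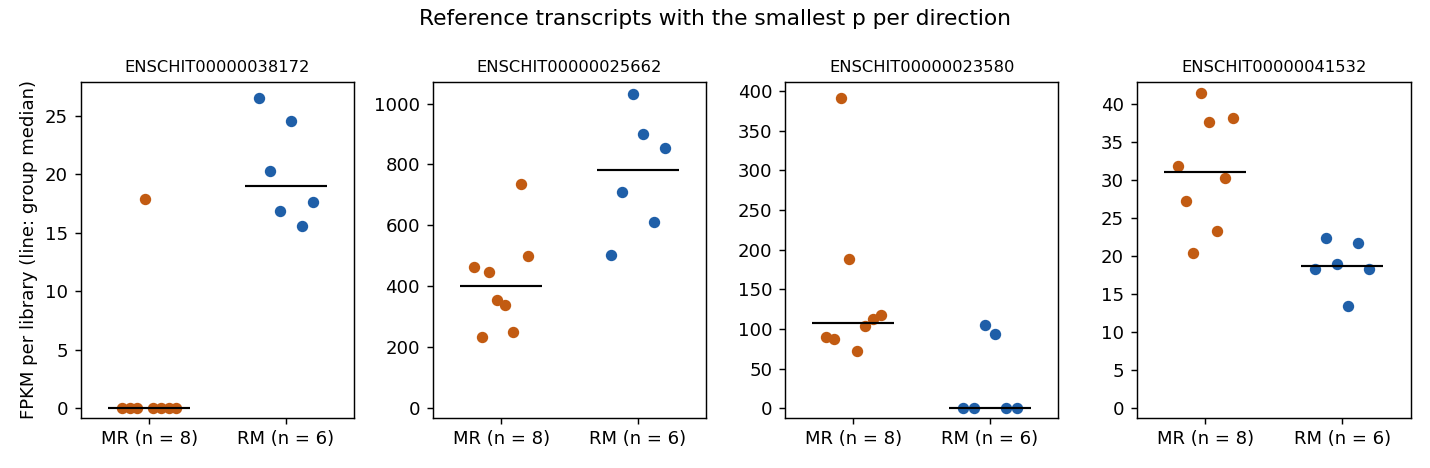
FPKM of 4 reference transcripts in each library of the MR (n = 8) and RM (n = 6) groups, with points for libraries and lines for group medians. ENSCHIT00000038172 is above 0 in 6 RM libraries and 1 MR library, and ENSCHIT00000023580 in 8 MR libraries and 2 RM libraries.

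Of the 7025 reference transcripts tested, 36 were listed more often in RM and 12 more often in MR at an unadjusted p under 0.05 (Fisher's exact test, two-sided), and 0 passed adjustment (smallest adjusted p = 1). With 6 against 8 libraries at least 47 transcripts would have to reach the smallest p of this test for any call, so the adjusted result says little. Values of 0 were frequent at all levels. Among transcripts with a median of 100 FPKM or more where above 0, 35.5% of values in MR and 32.8% in RM were 0.

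**Figure D3:**
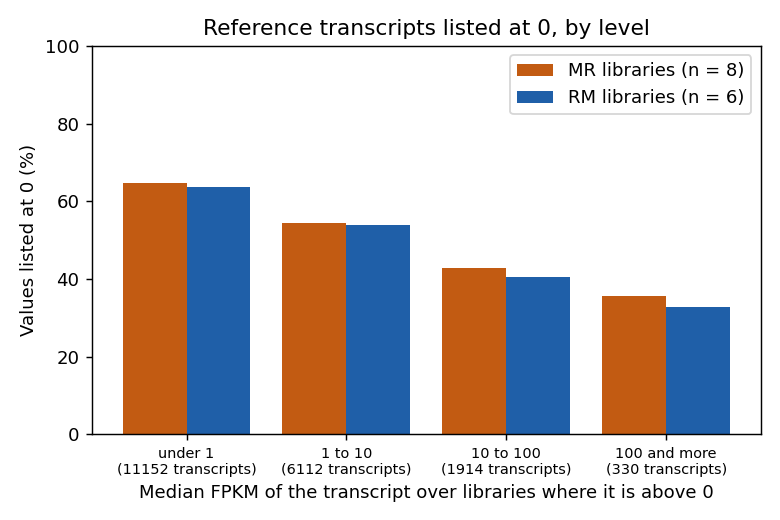
Share of values listed at 0 (%) among reference transcripts, by their median FPKM over the libraries where they are above 0, with bars for MR (n = 8 libraries) and RM (n = 6 libraries). The share falls from 64.8% in MR and 63.8% in RM under 1 FPKM to 35.5% and 32.8% at 100 FPKM or more.

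The question named in the series title concerns unannotated long non-coding RNAs, for which the table offers the CUFF rows. Among the 30665 CUFF rows tested, 0 differed between RM and MR by limma (smallest adjusted p = 0.857 over all rows and 0.814 over the class alone), with 573 higher and 291 lower in RM at an unadjusted p under 0.05. The 3 with the smallest p had log2 differences of -3.01 (SE 0.60), 2.44 (SE 0.51) and 2.40 (SE 0.51). CUFF rows carry no sign of coding or non-coding status here.

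The same CUFF identifier did not carry like values in different libraries. Over rows above 0 in both libraries of a pair, the Spearman correlation across rows had a median of 0.00233 over 91 pairs of libraries, with a range from -0.0271 to 0.0656. For reference transcripts it had a median of 0.953 and a range from 0.898 to 0.967 (rows are not independent replicates). The highest CUFF locus number differed in all 14 libraries, from 12080 to 22632. A test of a CUFF row between groups therefore compares values that need not belong to 1 transcript.

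**Figure D4:**
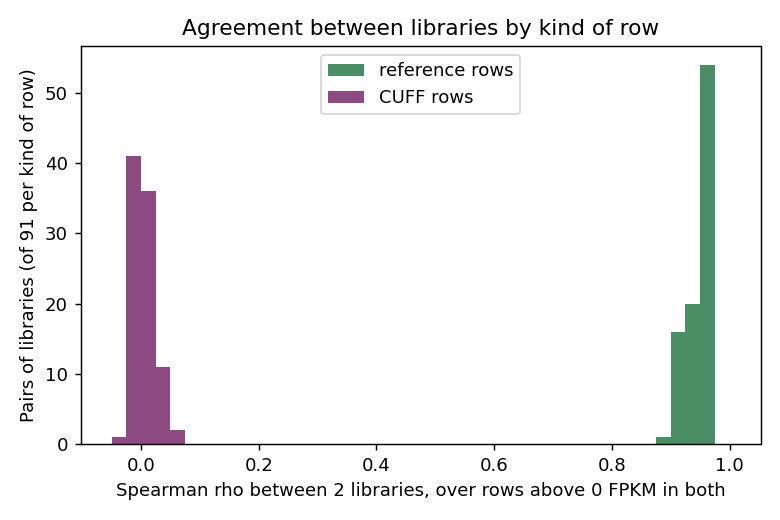
Number of library pairs by their Spearman correlation over rows above 0 FPKM in both, for reference rows and CUFF rows (91 pairs each). CUFF rows lie between -0.0271 and 0.0656, and reference rows between 0.898 and 0.967.

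CUFF rows were also listed unevenly. Their FPKM summed to 382616 ± 44037 (SD, n = 8) in MR and 312040 ± 49358 (SD, n = 6) in RM (exact permutation p = 0.0173, adjusted p = 0.0952 over 11 measures). Rows found in a single library numbered 1483 ± 394 per MR library (SD, n = 8) and 15.5 ± 26.2 per RM library (SD, n = 6; exact permutation p = 3.33e-04, the smallest these 3003 splits can give, adjusted p = 0.00366). After the last row of the first MR library, rows largely followed the column order of the libraries (Spearman rho 0.979), although the few first seen in RM replicates 9, 12, 13, 14 and 15 had median positions among the MR rows. The table ended at row 65535 soon after the first rows of the first RM column.

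**Figure D5:**
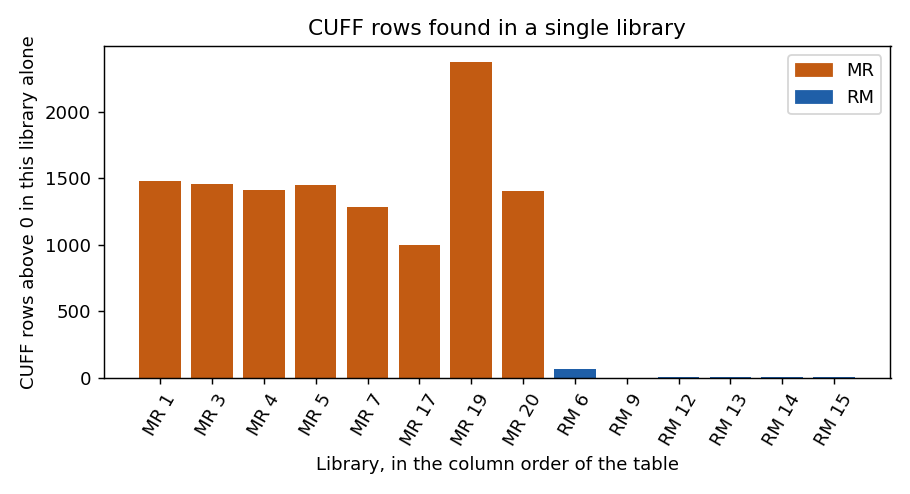
Number of CUFF rows above 0 in 1 library alone, for each library in the column order of the table. MR libraries have between 1000 and 2377 such rows, and RM libraries between 3 and 69.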

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

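Both explanations weighed in this part were tested after the result was seen. Across 36 checks of a library measure or named transcript within a group, 7 values, from 6 libraries, stood apart from the rest of their group by Dixon's criterion. Chance meets it in about 1 of 20 groups of normally distributed values. That rate does not hold for ENSCHIT00000038172, which was above 0 in only 1 MR library, so that its gap fills the range. Nor does it hold for CUFF rows found in a single library, which depend on where the table ended.

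CUFF rows found in a single library were few in RM, and the tables argue against fewer assembled loci in RM libraries as the whole cause. The mean highest locus number was higher in RM by 1737 (95% interval -1350 to 4800 by exact permutation), and a deficit in proportion to these rows would be -17482. A small deficit within that interval is not excluded. Of 3 tests tried for fewer loci, the one on locus numbers was the first. The others were dropped, 1 because it rested on a single library and 1 because it restated the pattern. A candidate explanation is that the table ended before rows of the RM libraries were added: row number and the position of the first library above 0 had a Spearman rho of 0.979 after the block of the first library, and 30605 of the later CUFF rows were first seen in an MR column against 141 in an RM column. Only 7 reference transcripts stood after that block, so their comparison is hardly touched by the end of the table, whereas CUFF counts, CUFF sums and the spread over CUFF rows are. Whether the feeding groups also differed in such rows stays open, since rows past the end of the table are not analysed here.

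MR replicate 19 had 2377 CUFF rows of its own, with the next MR library at 1483, and RM replicate 6 had 69, with the next RM library at 6. MR replicate 17 listed 8909 CUFF rows, with the next MR library at 14249, and it had the lowest relative depth, 0.766. In RM replicate 15 the 10 most abundant reference transcripts held 32.0% of reference FPKM, against 25.03% in the next RM library. RM replicate 14 had a first-component score of -11.4, with the next RM library at 1.85, and lay 19.4 log2 units from its group mean, against 14.7 for the next. MR replicate 5 was the single MR library with ENSCHIT00000038172 above 0, at 4.24 on the log2(FPKM + 1) scale, with the other 7 at 0.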

How the results depend on the processing

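The fits limited to reference transcripts and the one with values of 0 as missing were chosen after seeing the data. So were the rows up to the end of the first library and leaving out libraries over reference transcripts or over those above 0 in all libraries. The count of 0 rows called held under 14 other limma settings (smallest adjusted p between 0.0916 and 0.978) and in 13 of 14 fits that left out 1 library. Leaving out libraries gave between 0 and 1 calls, and the 1 call came without MR replicate 5 (ENSCHIT00000038172, adjusted p = 1.09e-04), where it is listed at 0 in the 7 remaining MR libraries, which then show no spread. The count among CUFF rows was also 0 under 12 other limma settings and in all 14 such fits. In simulated data the fit over all rows recovered 4% of 16-fold changes, and a CUFF identifier need not name 1 transcript. Counts of 0 that include CUFF rows therefore say little on a difference in those rows. The exact Mann-Whitney test also gave 0, but says little on this, since with these group sizes a call over all rows needs at least 252 rows at its smallest p. The separation of the groups stayed past no threshold under 7 other settings (exact permutation p from 0.456 to 1) and 14 omissions. The smaller spread of RM over all rows, -31.8 log2 units against MR, kept its side of the threshold but not its size with a pseudocount of 0.1 (-49.6), median-of-ratios scaling (-34.3), quantile normalization (-20.6) and a mean of at least 5 FPKM (-21.4), and lay between -39.3 and -24.4 when 1 library was left out, but these settings all keep the CUFF rows that depend on where the table ended, so they say nothing on its stability. Over the rows up to the end of the first library, without that library, it was -9.85 (exact permutation p = 0.181), or -4.87% of the MR distance. It no longer passed over reference transcripts (-6.39, exact permutation p = 0.437) or over those above 0 in all libraries (-4.43, exact permutation p = 0.0593). Distances grow with the number of rows, and at equal spread are somewhat smaller in RM, which has fewer libraries. As a percent of the MR distance these 2 differences came to -6.02% and -23.7%, against -11.0% over all rows. The cause of the last 2 changes was not tested. The 4 named transcripts kept their direction under all settings run, which is no separate support, since they were picked by their p from these same libraries. The size for those listed at 0 in many libraries was set largely by the pseudocount: with 0.1 FPKM the log2 difference was 6.70 for ENSCHIT00000038172 and -6.96 for ENSCHIT00000023580, against 3.85 and -4.75. Not run were the covariates built from gene lists and all alternatives for those lists and scores, since no transcript had a gene symbol, and the alternatives for counts, since the table holds FPKM. Relative depth differed by up to 1.58 times between libraries, and depth is known only as a mean. Recovery was lower in the set with values of 0: simulated changes of 4-fold were recovered in 15.5% of reference transcripts and in 96.5% of those above 0 in all libraries. The sets also differ in number (7025 and 1254 transcripts), and the 200 changed transcripts are a larger share of the smaller set, which eases its threshold. The part played by values of 0 was not tested apart.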

Other observations

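The tests of separate numbering and of the counts of called rows were chosen after the result was seen, and the others before.

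Chance is not excluded for the counts at an unadjusted p under 0.05. Of 100 splits of the 14 libraries into 6 and 8, the real one included, 95 gave at least its 1004 rows at an unadjusted p under 0.05 (highest other 1519). For reference transcripts 60 gave at least its 248 (highest other 611), and for those above 0 in all libraries 74 gave at least its 38 (highest other 239). For transcripts listed above 0 more often in 1 group, 87 gave at least its 48 (highest other 111). The real counts of calls over all rows (highest other 4) and over CUFF rows (highest other 1) were 0, which 100 of 100 splits reach by construction, so these splits test nothing there.

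CUFF values did not agree between libraries. Low and noisy values do not account for this: above 10 FPKM in both libraries the median rho was 0.00599 for CUFF rows and 0.853 for reference transcripts. The median rho of 0.00233 over all shared rows, with a different highest locus number in each of 14 libraries, is consistent with identifiers numbered separately in each library and then joined by name. In 7 libraries the CUFF row with the highest FPKM was also the last locus number of that library, under 7 different numbers. The tables argue against transcripts that differ between the feeding groups as the whole cause, since libraries fed alike did not agree either. The mean rho of CUFF rows was 0.00555 within groups and 0.00451 between groups, against 0.944 within groups for reference transcripts. A contribution of the feeding group stays open. Pairs within a group did not agree measurably better than pairs between groups (exact permutation p = 0.374), and the identifiers limit what such a test can see.

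Reference transcripts were often listed at 0 in some libraries and high in others. Among the 330 transcripts with a median of 100 FPKM or more where above 0, 34.3% of values were 0 and 235 had at least 1 value of 0. The tables argue against too few reads as the whole cause: in 38.2% of the 186 with a 0 and at least 3 values above it, these values varied less than counting error of few fragments allows (5% by chance), against 5.16% in transcripts of 0.3 to 1 FPKM run as a control, and at 23000000 reads per library 232 of the 235 would need an effective length under 1 base. An earlier test of pairs of like values (12.6% against 31.8% for few fragments) could not decide, since its control also fell short (8.18% against 38.4%), and one on the share of values at 0 was dropped because it restated the pattern. Fragments given to an assembled CUFF transcript of the same locus may be the source, which stays open. It was not tested because CUFF rows were not placed on genes here. The tables argue against the feeding group as the whole cause. Among the 330 transcripts, 35.5% of values in MR and 32.8% in RM were 0. Every library of either group listed between 100 and 135 of them at 0. Only 5 of the 330 were listed more often in 1 group (Fisher's exact test, unadjusted p under 0.05). A contribution of the feeding group stays open, with 7 of 100 splits giving as many (highest other 6).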
